A study of Homo sapiens with 4 samples.

How the data were processed

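RNA-seq was made from total RNA of MDA-MB-231 cells with TMEM126A knockdown or a control vector, and of Ca1a cells with TMEM126A overexpression or a control vector, per the labels. Constructs were delivered by lentivirus and RNA was extracted with TRIzol, per the labels' protocols. Each of the 4 groups held 1 library. HISAT2, Cufflinks, HTSeq and DESeq, and the builds GRCh38.p5 and hg38, are named in the submitters' processing notes. Their versions, order, roles and strand setting are not given in the sources used here.

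For Ca1a the authors deposited whole-number read counts per gene, as DESeq base means of single libraries per the file headers, with a size factor of 1. For MDA-MB-231 the deposited values are a signal: read counts per gene divided by the size factor of the library, as DESeq base means per the file headers. Every value of those columns was a whole multiple of the smallest value above 0, within a tolerance of 1e-06 (100% of values), and these multiples were taken as reads. The deposited tables also hold the authors' log2 fold changes and the authors' p-value and adjusted p-value per gene, which were copied and not recomputed. A further deposited table holds FPKM of all 4 libraries, made by the authors with a denominator that is not given in the sources used here. The tables hold 39261 genes by symbol. None of the 13 mitochondrially encoded protein genes is among them, so that list was not analysed here.

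Depth was 20673373 to 21405193 reads per library, and the most abundant gene took 0.537% to 0.661% of them. A count of 0 allows up to 3 reads. Sequenced fragments without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Levels carry exact Poisson intervals, and ratios carry exact conditional binomial (Clopper-Pearson) intervals at 95%.

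With 1 library per group no test between conditions was possible. Genes were called by a rule of size: a log2 ratio of at least 1 in either direction on log2(value + 1), a mean of at least 20 normalized counts, and a ratio interval that leaves out 1. Printed folds are ratios of normalized counts without the pseudocount. For 43 gene lists the median log2 ratio of the members passing the filter was placed among 10000 random lists of the same size, drawn from tested genes within 20 bins of mean expression. Lists with fewer than 3 such members were not placed. The groups, the rule of size, the lists and most alternative settings were fixed before the data were examined.

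Genes were named by rule: TMEM126A and TMEM126B, per comparison up to 12 protein-coding genes on each side that pass the rule of size with a mean of at least 100, up to 4 members per list with the largest absolute log2 ratios, up to 8 genes passing it in opposite and 8 in the same direction, and cell type markers. The rule gave 274 genes. The text gives examples from them, and 1 result was left out and is not reported here. TXNIP, PTGS2, TNFAIP3, SQLE, IL1A and IL1B (the last 3 in a plot), RPS18 and RPL7A, and the genes named in the closing observations on pathways, were chosen after their values were seen. Positions come from GENCODE release 29 on GRCh38, matched by Entrez gene ID.

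The calls were tested on simulated data: counts for 39261 genes were drawn from the means of each comparison, with 200 genes changed. For the knockdown comparison 96% of genes changed 2.5-fold and 100% of those changed 4-fold were recovered, and intervals covered the true ratio for 95.1% of genes. With 10% further variation between cultures the coverage was 54.9%. For the overexpression comparison 100% of genes changed 2.5-fold were recovered with a coverage of 95.7%, and 55.1% with the further variation.

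Alternatives were FPKM, pseudocounts of 0.5 and 5, a mean of at least 5, at least 100 or no filter, scaling by total reads, by the median or by TMM, thresholds of 1.5-fold and 3-fold, no counting interval, unmatched random lists, and the mean of a list. Removal of the trend on transcript length or GC content, protein-coding genes alone, and 1.5-fold with a mean of at least 100 were added after seeing the data. So were the counts of lists and pathways that independent placement would give. Software was python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM.

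Several limits follow from the counting. Reads of the TMEM126A construct and of the endogenous gene cannot be separated in the gene counts. Reads of overlapping genes, antisense partners and near-identical copies may be split or dropped, so RPS9, RPL7 and other ribosomal protein genes are uncertain. In all, 48 list members are listed at 0 in every table and library, among them RPS18 and RPL7A, which every cell uses, so a gene at 0 is only listed at 0.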

Results

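RNA from 4 cultures of human breast cancer cell lines was sequenced, with 1 library per culture. MDA-MB-231, a triple-negative line with a mesenchymal character, carried either a construct for TMEM126A knockdown or a control vector. MCF10-Ca1a (Ca1a), a malignant derivative of the MCF10A mammary epithelial line, carried either a TMEM126A overexpression construct or a control vector. The gene tables held 21405193 reads in the knockdown library and 20673373 in its control, 21359273 in the overexpression library and 21302171 in its control. There were no replicates, so no difference below has a replicate check and no p-value across genes was computed. Intervals are 95% counting intervals, which cover counting error only and leave out any difference between cultures unrelated to TMEM126A. Intervals left out a ratio of 1 for 28.1% of all tested genes in MDA-MB-231 and 34.3% in Ca1a, against 5% from counting error alone. Counts of list members beyond counting error below stand against at least those shares, which cover both directions and are not matched on expression. Intervals narrow as counts rise, so lists of abundant genes can exceed the shares without a shift. Cytosolic ribosomal protein genes, inside their random lists in Ca1a, had 19 of 45 members higher and 12 lower.

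The marker transcripts of the lines differed. Both Ca1a libraries expressed the epithelial adhesion gene EPCAM at 131 FPKM (a level scaled to transcript length and depth) in the control and 133 FPKM in the overexpression library. CDH1, the E-cadherin gene, stood there at 73.6 and 73.4 FPKM and the basal keratin gene KRT17 at 650 and 628 FPKM. In MDA-MB-231, CDH1 stood at 0.203 FPKM in the control and 0.332 FPKM in the knockdown library, the mesenchymal filament gene VIM at 721 and 708 FPKM, and the transcription factor gene ZEB1 at 8.31 and 8.07 FPKM. The epithelial keratin gene KRT19 went the other way, at 163 and 220 FPKM in the control and knockdown libraries of MDA-MB-231 and 1.04 and 1.61 FPKM in the control and overexpression libraries of Ca1a. The mesenchymal marker SPARC was low in all 4 libraries, at 0.278 to 0.563 FPKM. VIM was also expressed in Ca1a, at 90.5 FPKM in the control and 74.8 FPKM in the overexpression library. There the basal keratin gene KRT14 stood at only 0.0451 and 0.202 FPKM. In the control and knockdown libraries of MDA-MB-231 the epithelial keratin gene KRT8 stood at 112 and 127 FPKM and the mesenchymal marker CDH2 at 0.185 and 0.247 FPKM. Of 15 fibroblast, immune, endothelial and adipocyte markers, 14 were under 2 FPKM in all 4 libraries. The exception was CD68, a lysosomal protein gene used as a macrophage marker, at 28.9 to 98.6 FPKM. The endothelial marker PECAM1 was low but 1.88-fold higher (1.45 to 2.45) in the knockdown library and 1.66-fold higher (1.39 to 1.98) in the overexpression library.

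TMEM126A encodes a mitochondrial inner membrane protein that takes part in complex I assembly, and its level followed the labels in both lines. In MDA-MB-231 it had 22.9 normalized counts in the knockdown library (95% Poisson interval 14.5 to 34.3) and 559 in the control (514 to 608), which is 24.5-fold lower (16.1 to 38.9). In Ca1a it had 9381 counts in the overexpression library (9192 to 9573) and 265 in the control (234 to 299), which is 35.4-fold higher (31.3 to 40.1). The gene, Entrez 84233, is protein-coding, lies on chromosome 11 from 85647967 to 85656547 on the plus strand of GRCh38 and has 6 transcripts in GENCODE release 29. Its paralog TMEM126B, which encodes another complex I assembly factor, lies on the same strand from 85628573 to 85636539, with 11427 bp between the genes. TMEM126B had 1547 normalized counts in the knockdown library and 1597 in its control, a ratio of 0.969 (0.903 to 1.04). In Ca1a it had 702 counts in the overexpression library and 663 in the control, a ratio of 1.06 (0.951 to 1.18).

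**Figure D1:**
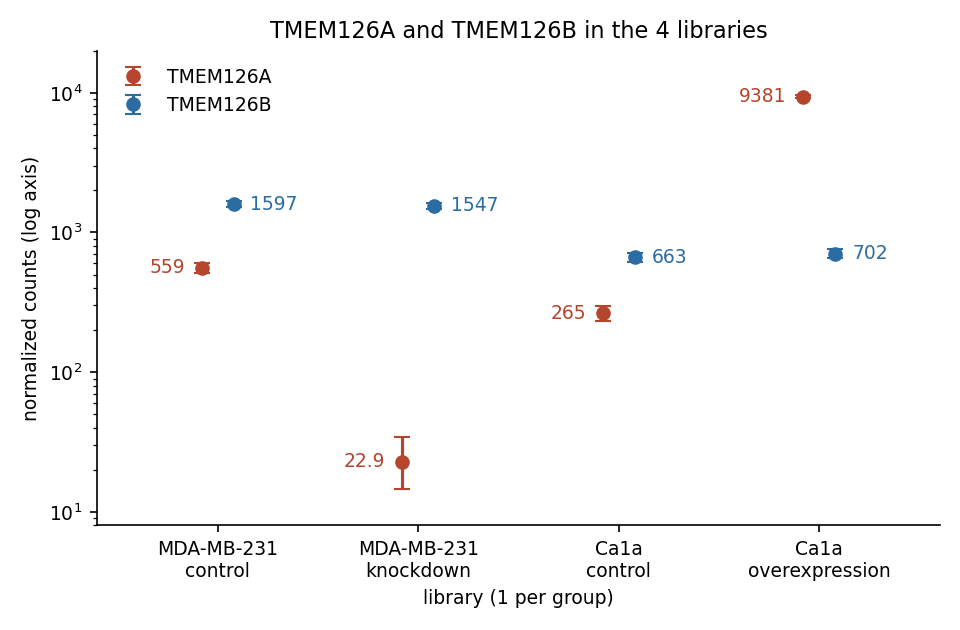
Normalized counts (log axis) of TMEM126A and TMEM126B in each of the 4 libraries, 1 library per group, with 95% Poisson intervals as error bars that cover counting error only. TMEM126A stood at 22.9 in the knockdown library against 559 in its control and at 9381 in the overexpression library against 265 in its control, while TMEM126B had ratios of 0.969 and 1.06.

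The first comparison asked which transcripts differed in MDA-MB-231 when TMEM126A was lowered. Endoplasmic reticulum chaperone, interferon-stimulated, NF-kB target, keratin and integrin genes were mostly higher in the knockdown library, and cholesterol synthesis genes and targets of the stress transcription factor ATF4 were mostly lower. AGR2, which encodes a protein disulfide isomerase of secretory epithelia, was 2.32-fold higher (1.98 to 2.73), and CST4, a salivary cystatin gene, 2.08-fold higher (1.72 to 2.51). ANGPTL4, which encodes an inhibitor of lipoprotein lipase, was 2.21-fold lower (2.0 to 2.45). Of 13292 genes with a mean of at least 20 normalized counts, 33 were at least 2-fold higher in the knockdown library and 19 at least 2-fold lower by the rule of size. Few of these were abundant: among protein-coding genes with a mean of at least 100, AGR2 and CST4 were higher, and TMEM126A and ANGPTL4 lower.

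Endoplasmic reticulum chaperone genes had a median log2 ratio of 0.26. Of 17 measured members, 15 were higher in the knockdown library beyond counting error, 0 were lower and 2 lay within it. SDF2L1 was 1.52-fold higher (1.34 to 1.73), CRELD2 1.44-fold higher (1.27 to 1.62) and HSPA5, which encodes the chaperone BiP, 1.25-fold higher (1.23 to 1.26). Interferon-stimulated genes had a median of 0.22, with 28 of 39 members higher, 1 lower and 10 within counting error. IFIT1 was 1.41-fold higher (1.34 to 1.49), OAS2, whose product senses double-stranded RNA, 1.38-fold higher (1.29 to 1.49) and TRIM22 1.38-fold higher (1.11 to 1.72). The antigen presentation list, of which 6 of 21 members were measured, had a median of 0.28, with 5 higher and 1 within counting error. The antigen presentation genes HLA-E, HLA-F, TAP1 and PSMB9 are listed at 0 in every library, so much of this function was not measured. The cause of these zeros was not tested. B2M, the light chain of MHC class I, was 1.29-fold higher (1.24 to 1.33) and CIITA, the activator of MHC class II genes, 1.24-fold higher (1.12 to 1.37).

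NF-kB targets and cytokines had a median of 0.18, with 15 of 27 members higher, 3 lower and 9 within counting error. CCL20, a chemokine gene, was 1.73-fold higher (1.36 to 2.20) and CSF1, a macrophage growth factor gene, 1.43-fold higher (1.39 to 1.47). Among genes of breast cancer lung metastasis the median was 0.25, with 8 of 15 members higher, 2 lower and 5 within. VCAM1, an adhesion receptor gene, was 2.42-fold higher (1.64 to 3.62), KYNU 1.62-fold higher (1.47 to 1.78) and ID1 1.49-fold higher (1.40 to 1.60), whereas ANGPTL4 and the interstitial collagenase gene MMP1 were lower, MMP1 1.44-fold lower (1.31 to 1.58). Keratin genes had a median of 0.26, with 7 of 10 higher, 0 lower and 3 within, among them KRT81, 1.44-fold higher (1.40 to 1.48), and KRT19, 1.39-fold higher (1.34 to 1.45).

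Matrix and adhesion lists had smaller medians than the lists above, although single members differed by larger amounts. Integrin genes had a median of 0.15, with 10 of 15 higher, 1 lower and 4 within counting error. ITGB8 was 2.47-fold higher (1.30 to 4.97) on few counts, ITGB1 1.21-fold higher (1.19 to 1.23) and ITGAV 1.21-fold lower (1.16 to 1.27). Collagen genes had a median of 0.12, with 10 of 20 higher, 3 lower and 7 within. COL6A1 was 1.37-fold higher (1.31 to 1.43) and COL27A1 1.32-fold lower (1.2 to 1.46). Other matrix protein genes also had a median of 0.12, with 17 of 29 higher, 3 lower and 9 within. The laminin chain gene LAMA5 was 1.40-fold higher (1.36 to 1.44) and the lumican gene LUM 2.45-fold lower (1.41 to 4.43). Matrix crosslinking genes had a median of 0.11, with 9 of 15 higher, 0 lower and 6 within, and the lysyl oxidase gene LOXL4 was 1.49-fold higher (1.43 to 1.55). Mesenchymal genes had a median of 0.10, with 9 of 21 higher, 2 lower and 10 within. CDH11 was 1.34-fold higher (1.26 to 1.43) and S100A4 1.31-fold higher (1.26 to 1.37), whereas TAGLN was 1.38-fold lower (1.19 to 1.61). Nuclear-encoded subunits of complexes II to V had a median of 0.06, with 9 of 37 higher, 0 lower and 28 within, and UQCR11 was 1.16-fold higher (1.08 to 1.24).

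Cholesterol synthesis genes had a median log2 ratio of -0.16 in the knockdown comparison. Of 32 measured members, 18 were lower in the knockdown library beyond counting error, 0 were higher and 14 lay within it. INSIG1, a sterol-regulated retention factor, was 1.51-fold lower (1.37 to 1.67) and SREBF2, the transcription factor gene of the pathway, 1.45-fold lower (1.36 to 1.54). ATF4 targets had a median of -0.12, with 20 of 31 lower, 3 higher and 8 within counting error. CHAC1, which encodes a glutathione-degrading enzyme, was 1.82-fold lower (1.59 to 2.10), SLC7A11, the cystine transporter gene, 1.48-fold lower (1.40 to 1.56) and SESN2 1.44-fold lower (1.28 to 1.62).

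In the knockdown comparison 14 of 41 lists lay outside the central 95% of 10000 random lists matched on mean expression. Of these, 12 lay above and 2 below, and lists of unrelated genes would give 2.05 outside. Genes of a list that vary together between cultures would give more, so the excess is no measure of an effect of TMEM126A. Complex I subunits (median 0.02), complex I assembly factors (-0.01, with a mean of 0.03), the mitochondrial ribosome (-0.01), the TCA cycle (0.04) and S phase genes (-0.01) were inside. The percentile is a description of these libraries, and the calls of complexes II to V, collagens, other matrix proteins, matrix crosslinking and mesenchymal genes ended under at least 1 alternative setting. Beside the 52 genes past 2-fold, simulated libraries gave 16 calls among unchanged genes from counting error alone and 30 with 10% further variation between cultures. On average over genes, that variation was wider than in these libraries. Every simulated gene was given the same variation, so 30 is no upper bound on such calls. Simulated intervals covered the true ratio for 54.9% of genes, while 28.1% of the real intervals left out 1.

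**Figure D2:**
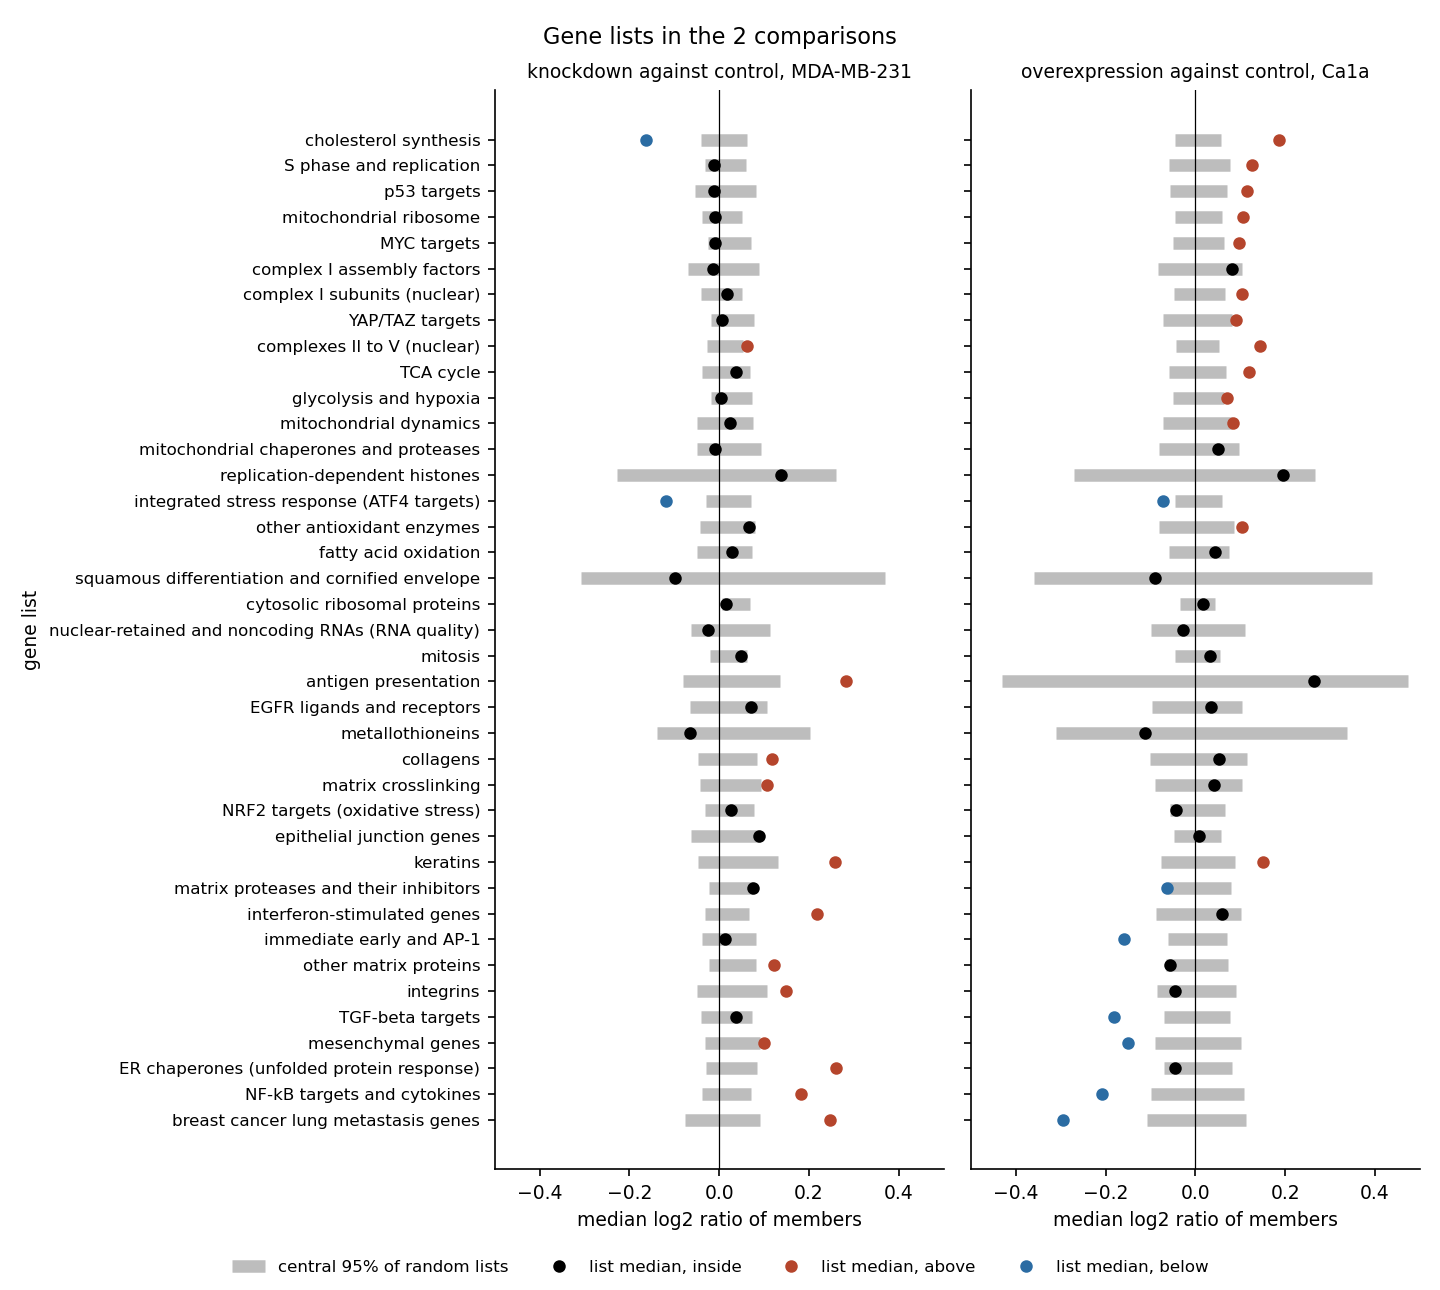
Median log2 ratio (treated over control) of the 39 gene lists tested in both comparisons, with grey bars for the central 95% of 10000 random lists matched on mean expression, from 1 library per group. Cholesterol synthesis had a median of -0.16 in the knockdown comparison and 0.19 in the overexpression comparison, and the lung metastasis list 0.25 and -0.30.

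The second comparison asked which transcripts differed in Ca1a when TMEM126A was raised. More than 50% of the measured cholesterol synthesis, complex II to V, TCA cycle, mitochondrial ribosome, keratin and p53 target genes were higher in the overexpression library beyond counting error. More than 50% of lung metastasis genes, TGF-beta targets and immediate early genes were lower. CTGF, a matricellular growth factor gene, was 2.28-fold higher (1.69 to 3.11) and IL7R, a cytokine receptor gene, 2.11-fold higher (1.61 to 2.79). AGR2, higher in the knockdown library, was here also 1.43-fold higher (1.10 to 1.88). BMP6, a bone morphogenetic protein gene, was 2.07-fold lower (1.68 to 2.56) and IL11 2.05-fold lower (1.55 to 2.74). Of 12111 genes tested, 31 were at least 2-fold higher and 35 at least 2-fold lower by the rule of size. Among protein-coding genes with a mean of at least 100, TMEM126A, CTGF and IL7R were higher, and BMP6 and IL11 lower.

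Cholesterol synthesis genes had a median log2 ratio of 0.19 in the overexpression comparison, with 21 of 30 members higher, 0 lower and 9 within counting error. LSS, the lanosterol synthase gene, was 1.42-fold higher (1.29 to 1.57), ACLY, whose enzyme makes cytosolic acetyl-CoA, 1.31-fold higher (1.28 to 1.35) and FDFT1, the squalene synthase gene, 1.30-fold higher (1.28 to 1.32). Subunits of complexes II to V had a median of 0.15, with 27 of 37 higher, 1 lower and 9 within. COX7B was 1.28-fold higher (1.18 to 1.38) and UQCR10 1.22-fold higher (1.09 to 1.35), whereas ATP5D was 1.21-fold lower (1.13 to 1.30). Complex I subunits had a median of 0.10, with 13 of 35 higher, 0 lower and 22 within, led by NDUFS5, 1.30-fold higher (1.22 to 1.38). Complex I assembly factors had a median of 0.08, inside their random lists, with 3 of 16 higher and 13 within. TCA cycle genes had a median of 0.12, with 12 of 20 higher, 1 lower and 7 within, among them PDHB, 1.28-fold higher (1.2 to 1.36), and IDH3B, 1.2-fold higher (1.13 to 1.28). Mitochondrial ribosome genes had a median of 0.11, with 17 of 32 higher, 2 lower and 13 within, and MRPL20 was 1.25-fold higher (1.15 to 1.36).

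Keratin genes had a median of 0.15, with 9 of 14 higher, 4 lower and 1 within. KRT80 was 1.47-fold higher (1.34 to 1.60) and KRT10 1.30-fold lower (1.04 to 1.64). S phase genes had a median of 0.13, with 12 of 30 higher, 2 lower and 16 within. TYMS, the thymidylate synthase gene, was 1.35-fold higher (1.22 to 1.49) and CCNE1, the cyclin E gene, 1.76-fold lower (1.21 to 2.59). p53 targets had a median of 0.12, with 13 of 23 higher, 2 lower and 8 within, and SESN1 was 1.41-fold higher (1.26 to 1.57). MYC targets had a median of 0.10, with 14 of 25 higher, 2 lower and 9 within, although ODC1, the ornithine decarboxylase gene, was 1.26-fold lower (1.21 to 1.30). Other lists above their random lists were antioxidant enzymes (median 0.10, 7 of 15 higher and 1 lower) and YAP/TAZ targets (0.09, 8 of 21 higher and 3 lower). So were mitochondrial dynamics (0.08, 8 of 16 higher and 1 lower) and glycolysis and hypoxia (0.07, 16 of 29 higher and 6 lower). In the last of these NDRG1, a hypoxia-responsive gene, was 1.92-fold lower (1.84 to 2.01).

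Genes of breast cancer lung metastasis had a median of -0.30 in the overexpression comparison, with 9 of 13 members lower, 2 higher and 2 within. ANGPTL4 was 1.47-fold lower (1.37 to 1.57) and the chemokine gene CXCL1 1.49-fold lower (1.07 to 2.10). NF-kB targets had a median of -0.21, with 9 of 21 lower, 2 higher and 10 within. CXCL2 was 1.72-fold lower (1.36 to 2.18) and CXCL3 1.64-fold lower (1.11 to 2.44). TGF-beta targets had a median of -0.18, with 12 of 22 lower, 4 higher and 6 within. LTBP1 was 1.44-fold lower (1.27 to 1.63) and TGFB1 2.12-fold lower (1.54 to 2.95), whereas TGFB2 was 2.0-fold higher (1.46 to 2.76). Immediate early genes had a median of -0.16, with 13 of 22 lower, 4 higher and 5 within. JUNB was 1.54-fold lower (1.47 to 1.61) and EGR1 1.43-fold lower (1.35 to 1.52), whereas FOSB was 1.73-fold higher (1.19 to 2.56). Mesenchymal genes had a median of -0.15, with 7 of 22 lower, 3 higher and 12 within. SNAI2, the Slug gene, was 1.54-fold lower (1.46 to 1.62) and FAP 1.60-fold higher (1.16 to 2.23). ATF4 targets had a median of -0.07, with 15 of 31 lower, 2 higher and 14 within, and CEBPB was 1.73-fold lower (1.64 to 1.84). Endoplasmic reticulum chaperone genes had a median of -0.04, inside their random lists, with 8 of 17 lower, 2 higher and 7 within, and HSPA5 was 1.22-fold lower (1.19 to 1.24). They lay below their random lists with FPKM and with the mean of the members. Matrix proteases and their inhibitors had a median of -0.06, with 10 of 24 lower, 8 higher and 6 within, which turned to 0.01 with FPKM.

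In the overexpression comparison 20 of 39 lists lay outside the central 95% of their random lists, 13 above and 7 below. Lists of unrelated genes would give 1.95, and genes of a list that vary together between cultures would give more. Calls ended under at least 1 alternative setting for 10 of the 20: mitochondrial dynamics, ATF4 targets, antioxidant enzymes, glycolysis, matrix proteases, mesenchymal genes, TGF-beta, YAP/TAZ and MYC targets, and NF-kB targets. Beside the 66 genes past 2-fold, simulated libraries gave 5 calls among unchanged genes from counting error alone and 20 with 10% further variation between cultures. Here too that variation was wider than in the libraries on average over genes, with a simulated coverage of 55.1% while 34.3% of the real intervals left out 1. It was the same for every gene, so 20 is no upper bound.

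**Figure D3:**
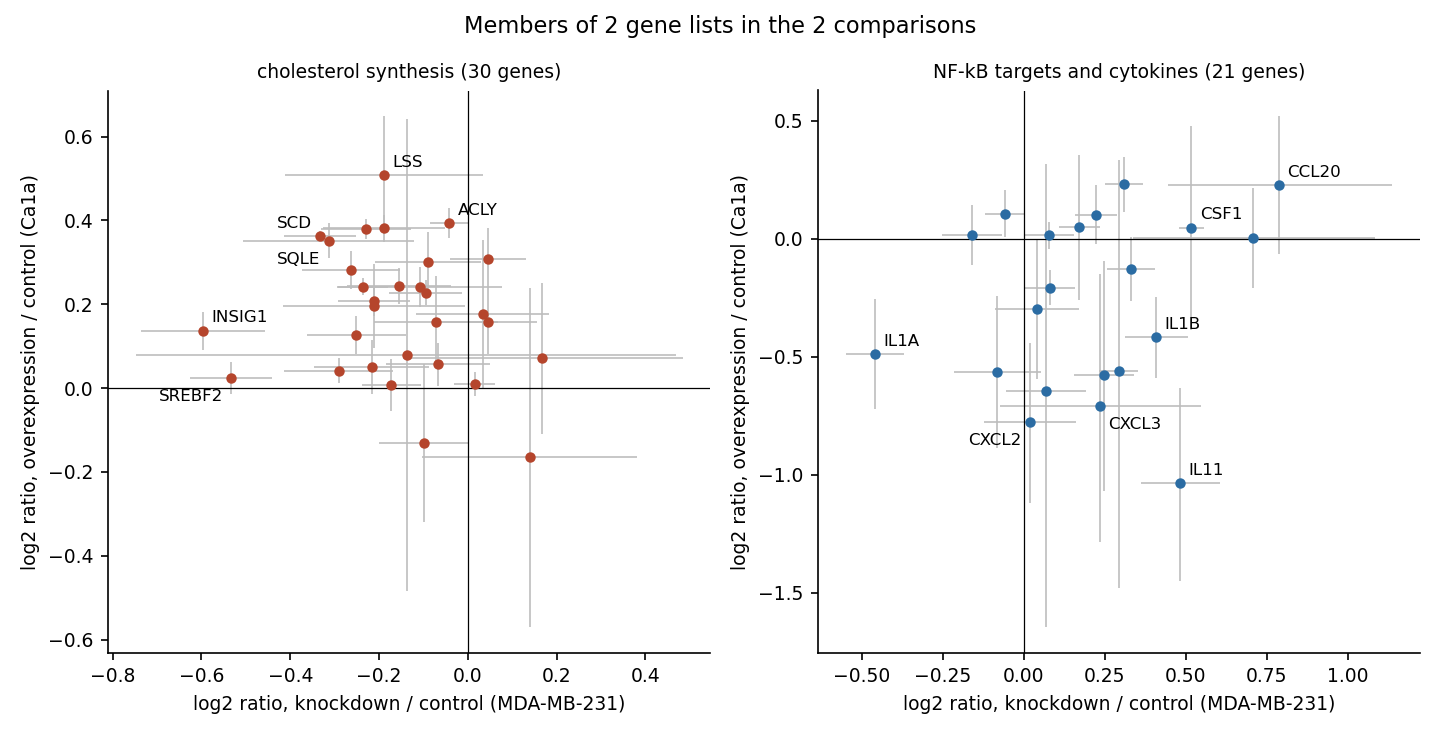
Log2 ratios (treated over control) of 30 cholesterol synthesis genes and 21 NF-kB targets tested in both comparisons, knockdown on the horizontal and overexpression on the vertical axis, 1 library per group, with grey bars for 95% counting intervals. Of the cholesterol synthesis genes, 23 were lower in the knockdown library and higher in the overexpression library, and of the NF-kB targets 10 were higher in the knockdown library and lower in the overexpression library.

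Set side by side, the comparisons shared no library, and a gene following the level of TMEM126A would differ in opposite directions. Apart from TMEM126A, 1 gene did so by the rule of size: PHEX, which encodes an endopeptidase of phosphate balance, was 2.22-fold higher (1.2 to 4.29) in the knockdown library and 2.5-fold lower (1.37 to 4.78) in the overexpression library, on 16.1 to 40 counts. Independent calls would give 0.0190 genes higher in the knockdown and lower in the overexpression library, if every tested gene were equally likely to be called. Most calls, PHEX among them, fell on genes with low counts, so that number is likely too low. In the same direction 0 genes passed in both comparisons. Across 11348 genes without TMEM126A, Pearson's correlation of the log2 ratios was 0.041 and Spearman's 0.039, across genes, which are not independent replicates. Shuffling of genes gave Spearman's correlation a 95% bound in size of 0.0183. The observed value lay beyond it, on the side of the same direction, although shuffling treats genes as independent. Opposite signs were found for 5422 genes and the same sign for 5824.

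Cholesterol synthesis, NF-kB target, lung metastasis and mesenchymal genes lay on opposite sides of their random lists in the comparisons, which makes 4 of 39 lists tested in both, where independent placement would give 2.82. On the same side were 3 lists, with 4.36 given by independent placement: complexes II to V and keratins above in both, and ATF4 targets below in both. Of 30 cholesterol synthesis genes tested in both, 24 had opposite signs, 23 of them lower in the knockdown and higher in the overexpression library. HMGCS1, the cytosolic HMG-CoA synthase gene, was 1.14-fold lower (1.04 to 1.25) and 1.30-fold higher (1.27 to 1.33) in the knockdown and overexpression libraries, and SCD, a fatty acid desaturase gene, 1.26-fold lower (1.19 to 1.33) and 1.29-fold higher (1.27 to 1.30). Opposite signs were found for 12 of 21 NF-kB targets, 9 of 12 lung metastasis genes and 12 of 19 mesenchymal genes. Over all genes tested in both comparisons the share was 47.8%. Lists not on opposite sides reached shares as high as the NF-kB and mesenchymal lists, such as epithelial junction (16 of 24) and S phase genes (19 of 30). Lists inside their random lists in both comparisons included mitosis genes (medians 0.05 and 0.03), epithelial junction genes (0.09 and 0.01), cytosolic ribosomal protein genes (0.01 and 0.02) and the noncoding RNAs used as a sign of RNA quality (-0.02 and -0.03). Some of these lay outside under an alternative setting: the RNA quality list in the knockdown comparison with FPKM, epithelial junction genes there with unmatched random lists and with the mean of the members, and ribosomal protein genes there without the length trend and in the overexpression comparison with the mean of the members. The NF-kB and lung metastasis lists share 3 genes, CXCL1, PTGS2 and TNFAIP3.

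The authors' deposited table for MDA-MB-231 listed 50 of 21619 genes with a DESeq adjusted p under 0.05, 38 higher and 12 lower in the knockdown library. For Ca1a, the authors' deposited table listed 24 of 18801 genes, 8 higher and 16 lower in the overexpression library. TMEM126A had an adjusted p of 3.84e-55 and 2.03e-175 in the authors' deposited table for each line. ANGPTL4 had an adjusted p of 8.72e-11 for MDA-MB-231 and NDRG1 8.38e-07 for Ca1a in the authors' deposited table. Besides TMEM126A, the gene listed in both was TXNIP, an arrestin-family gene induced by glucose, with log2 fold changes of 0.52 and -0.73 in the authors' deposited table. These p-values come from single libraries, so they compare the libraries and not the conditions.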

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

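The tests on the mesenchymal list and the number of opposite lists from independent placement were chosen only after the results were seen.

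In the FPKM table, which the counts of genes do not use, 35 genes had at least 10 FPKM in all 4 libraries while the count tables gave them a mean under 20 in both comparisons. They include ATP5E at 337 to 712 FPKM, NME2 at 274 to 328 FPKM and EIF4A1 at 217 to 250 FPKM, and 10 carry the joined name of a readthrough pair. Exons shared with another gene on the same strand are a candidate explanation, since a read that falls on both genes can be left uncounted: 97.0% of the 33 with annotation share exonic bases, against 17.9% of 3518 other genes at that FPKM. ATP5E is the exception, with no shared exon in the annotation. No biological explanation was tested, and these genes are not measured by the counts.

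The lists of complex I subunits, complexes II to V, TCA cycle and mitochondrial ribosome genes were higher in the overexpression library. A transcript length bias alone and a GC content bias alone are argued against as the whole cause, since 4 of 4 lists stayed above their random lists with either trend removed. The complex I median, however, went from 0.103 to 0.0672 without the length trend (upper random bound 0.0560). Trends were removed 1 at a time, with the length and GC content of the longest annotated transcript. A joint bias, or one of the transcripts in use, was therefore not tested. The authors' way of counting is argued against likewise, with 4 of 4 above in FPKM, where the mitochondrial ribosome median was 0.0515 in place of 0.106 (upper random bound 0.0451). A difference between the cultures other than TMEM126A stays open, because there was 1 library per group, and cannot be told apart from an effect of TMEM126A.

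Cholesterol synthesis, NF-kB target, lung metastasis and mesenchymal lists lay on opposite sides in the comparisons. With the trend on transcript length removed, 3 of 4 stayed on opposite sides, joined there by MYC targets, with the GC content trend removed 3 of 4, and with the authors' way of counting by FPKM 4 of 4, joined there by endoplasmic reticulum chaperones. With a mean of at least 100, NF-kB targets left and matrix proteases joined; with the mean of the members, mesenchymal genes left and endoplasmic reticulum chaperones joined; and the NF-kB median in the overexpression comparison went from -0.207 to -0.133 without the GC trend. The mesenchymal list was the one that ended without the length or GC trend: its median in the knockdown comparison was 0.0996 against an upper random bound of 0.0911, and became 0.0675 with the length trend removed (bound 0.0805) and 0.0732 with the GC trend removed (bound 0.0761), so a length or GC content bias stays open for it. A hypothesis that these lists follow TMEM126A may hold, but 4 opposite lists stand beside 2.82 from independent placement, and with 1 library per group a difference between the cultures cannot be told apart from it.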

How the results depend on the processing

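The protein-coding genes alone, the removal of length or GC trends, and 1.5-fold with a mean of at least 100 were chosen after the data were seen. Over all alternatives, 89 values that answer a comparison stayed within their bounds, 16 were larger, 19 smaller and 2 moved. List medians stayed in 1089 cases, moved in 17 and turned in sign in 1. Many of these could hardly move: unmatched random lists leave every median unchanged, and scaling shifts all genes by nearly the same small amount. List calls were less stable: 5 of 14 in the knockdown and 10 of 20 in the overexpression comparison ended under at least 1 alternative. Named genes were checked with FPKM alone, where 445 values stayed, 61 moved and 1 turned in sign. Counts run in this order: genes at least 2-fold higher in the knockdown library (33), genes at least 2-fold lower in the knockdown library (19), genes at least 2-fold higher in the overexpression library (31), genes at least 2-fold lower in the overexpression library (35), and genes that differ in opposite directions in the 2 comparisons (2). A mean of at least 5 gave 113, 97, 84 and 82, with 3 opposite; no filter gave 139, 122, 100 and 94, with 4 opposite. A mean of at least 100 gave 3, 2, 3 and 3, with 1 opposite, since fewer genes were tested. A threshold of 1.5-fold gave 189, 99, 151 and 156, with 5 opposite, and 3-fold gave 0, 1, 6 and 4, with 1 opposite. A pseudocount of 5 gave 14, 11, 20 and 27, with 1 opposite, since it shrinks low genes. FPKM gave 16, 17, 11 and 8, with 1 opposite. Its rule differed: 1 was added to FPKM, at least 1 FPKM was needed in at least 1 library of a comparison, and no counting interval was used. Adding 1 FPKM also shrinks low genes, and how much each difference contributed was not tested. The 1.5-fold threshold with a mean of at least 100 gave 68, 25, 44 and 58, with 1 opposite. Spearman's correlation was 0.080 in FPKM and 0.019 without a filter, and the cause was not tested. The median of the matrix protease list in the overexpression comparison was 0.0108 in FPKM, and RPL7 had a log2 ratio of -0.0829 in FPKM in the knockdown comparison, each turned in sign, and the cause was not tested. Scaling by total reads, the median or TMM ended no list call. Such scaling moves a list and its random lists by nearly the same amount, so it could hardly end one. No paired analysis was possible because each group held 1 library, and no replicate could be left out. Depth limits genes under a mean of 100, which made up most 2-fold calls.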

Other observations

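The pathways and genes named here, and the counts from independent placement, were chosen only after the results were seen. Among 267 KEGG pathways in the knockdown comparison, 48 lay above and 8 below the central 95% of their random lists. Sets of unrelated genes would give 6.68 on each side, and genes of a pathway that vary together would give more. In ECM-receptor interaction, matrix proteins and their receptors, 32 of 48 genes were higher in the knockdown library beyond counting error and 2 lower, with a median log2 ratio of 0.12. In N-glycan biosynthesis, the making of sugar chains on secreted proteins, 22 of 45 genes were higher and 0 lower (median 0.09), among them MAN1A1, ALG5 and RPN1. In chondroitin and dermatan sulfate biosynthesis 7 of 18 genes were higher and 0 lower (median 0.13). In the complement and coagulation pathway 11 of 24 genes were higher and 2 lower (median 0.11), with the complement genes C1R, C1S and C3 among the higher ones.

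Among 261 pathways in the overexpression comparison, 37 lay above and 47 below. Sets of unrelated genes would give 6.53 on each side. Spliceosome genes, whose products remove introns, had 63 of 119 members higher in the overexpression library and 5 lower (median 0.11), among them SNRPG, LSM3 and TRA2A. Propanoate metabolism had 15 of 24 genes higher and 0 lower (median 0.16), and degradation of valine, leucine and isoleucine 18 of 39 higher and 2 lower (median 0.10), with ALDH6A1, ACADM and HIBCH in both. On the other side were chemokine signalling, with 28 of 86 genes lower and 8 higher (median -0.06), and Notch signalling, with 13 of 38 lower and 4 higher (median -0.06), including MFNG and HES1. Pathways share genes, so these counts are not independent of each other or of the lists. Spearman's correlation of the log2 ratios with transcript GC content was 0.132 in the knockdown and -0.160 in the overexpression comparison. With transcript length it was -0.103 and -0.0590. Pathways were not placed with these trends removed, so a length or GC content bias stays open for them.

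Across 259 pathways placed in both comparisons, 10 lay on opposite sides, where independent placement would give 9.17, and 10 on the same side, where it would give 7.93. In this wider set, opposite placement was therefore about as frequent as for unrelated comparisons. TNF signalling and focal adhesion were above in the knockdown and below in the overexpression comparison, and RNA degradation and RNA transport the other way. Oxidative phosphorylation, pyruvate metabolism and lysosome were among the 9 pathways above in both. The KEGG sets nearest to lists on opposite sides did not all repeat that placement. The NF-kappa B signalling pathway was inside its random lists in both, with 13 genes higher and 10 lower in the knockdown library and 14 higher and 10 lower in the overexpression library. Steroid biosynthesis (5 lower, 2 higher) and terpenoid backbone biosynthesis (6 lower, 5 higher) were inside in the knockdown comparison and above in the overexpression comparison, with 11 and 10 genes higher and 1 lower in each.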
